A study of Mus musculus with 6 samples.

How the data were processed

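The series holds 6 sequencing libraries from adult mice with a global knockout of Fto, the gene of an RNA demethylase that acts on N6-methyladenosine (m6A), on a C57BL/6 background. Per the labels' protocols, RNA came from midbrain and striatum, ribosomal RNA was depleted, and m6A-containing RNA was immunoprecipitated in consecutive rounds with an m6A antibody (MeRIP). The 6 libraries are 3 MeRIP libraries and 3 input libraries without immunoprecipitation, numbered 1 to 3 in both groups by their titles. Every sample's description names the same processed file, so the values used here are 1 peak list for all libraries.

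The authors' deposited list gives a chromosome, a start and an end for each region in 3 columns without a header line, and these coordinates are the only values in it. It has no read count, height, fold, p-value, strand, gene name or value per replicate. Per the submitters' processing notes, BWA 0.6.2-r126 and SAMtools 0.1.18 were used and the genome build was mm9. The peak caller, its threshold and the way in which replicates were combined are not given in the sources used here. The read depth of the libraries is unknown from the list, so no depth-based interval or detection floor could be attached to a peak. Absence of a peak can reflect low transcript level or low depth as well as low methylation. The list holds no separate background value from the input libraries, and how they entered the peak calling is not given in the sources used here.

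Coordinates are given in mm9, 1-based. No mm9 genome or gene annotation was used here. Gene numbers per chromosome came from a RefSeq gene table of GRCm38.p6, from which only the chromosome, biotype and symbol of each protein-coding gene were taken, and the order of neighbouring genes on chromosome 18. No coordinate was compared between the builds. The analyses planned before the data were examined that need genes or sequence were therefore not run. These were the position of peaks along transcripts, the m6A sequence motif, and the share of fixed brain, synaptic, glial and m6A-enzyme gene lists with a peak. The correlation of peak score with length was not run because the list has no score. The state of the Fto locus, the usual check of a knockout label, was not analysed here because peaks could not be assigned to genes without an mm9 annotation.

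Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Neighbouring peaks that touched (a gap of 0 bp) were merged into stretches. Clusters were formed by joining peaks separated by at most 5 kb. The share of peaks with another peak within 1 kb was compared with 1000 random placements of the same peaks within the span of peaks on their own chromosome, in a one-sided permutation test whose smallest possible p is 0.001. Peaks per chromosome were compared with protein-coding genes over chromosomes 1 to 19 and X, with Pearson's r and Spearman's rho and two-sided permutation tests of 100000 resamples, whose smallest possible p is 1e-05. Benjamini-Hochberg adjustment covered the 2 relations computed, with gene number and with the span of peaks. Exact Poisson and exact binomial (Clopper-Pearson) 95% intervals cover counting error only, and treat peaks as independent although they lie in groups, so they are too narrow. The interval of each chromosome's mean stretch length came from 10000 bootstrap resamples of its stretches. Differences between X and each autosome in stretch length, and in the percentage of stretches over 200 bp, have 95% intervals from 10000 bootstrap resamples of 5 kb clusters, so that neighbouring stretches stayed together. They are not adjusted for the 19 comparisons, which all share the stretches of X. This comparison of X was chosen after the values had been seen and is the last of 3 criteria applied to them. The first, the upper bound of X against the lowest autosomal mean, also set X apart in stretch length. The second, separate intervals that do not overlap, did not, since that of chromosome 16 (211.4 to 230.2 bp) overlaps that of X (189.9 to 212.5 bp).

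The rule for named items, fixed before the data were examined, fell back to coordinates because peaks could not be assigned to genes. It named the 10 longest and the 5 longest peaks, and the 5 windows of 100 kb with the most peaks. Peak midpoints were counted in windows aligned to multiples of 100 kb. Because 2969 peaks shared the greatest length of 200 bp, the longest peaks were not defined, and the 10 longest merged stretches were named in their place after the lengths had been seen. Alternatives were listed peaks at or above the median length, merged peaks, other distances, covered bases, autosomes only, and gene numbers without chemosensory receptor, predicted, clone-named and multicopy genes. The last filter was applied by gene symbol on every chromosome, but its multicopy families were chosen mainly for X, and it removed 34.2% of protein-coding genes there against 6.06% to 27.2% on the autosomes. Most of its patterns match only the first letters of a symbol, so it can also leave out genes outside these families. Whether the genes left out are transcribed in brain was not examined. The filter changes the gene number only, since the peaks of the genes left out could not be removed. The functions were tested on simulated data. All 4000 of 4000 simulated stretches were recovered from their parts. The clustering test called 10 of 10 simulated lists with 200 neighbours placed close together and 0 of 10 random lists, each of 29905 peaks. The correlation test called 20 of 20 simulated sets drawn from gene number and 0 of 20 with shuffled gene numbers. The bootstrap of differences called 20 of 20 simulated pairs of chromosomes with a shift of 50 bp and 1 of 20 without a shift. Only calls of a shorter mean on the first chromosome were counted, so calls in the other direction are not in these numbers. Each simulated chromosome held 600 stretches with independently drawn lengths, whereas X had 437. The simulated lengths were drawn evenly over a narrow range, whereas real lengths had an SD of 119.7 bp on X and reached 2075 bp on the autosomes. The simulated counts therefore do not give the error rates for the real lengths. The observed differences from X, 19.6 to 47.5 bp, were all smaller than 50 bp, so the power at those sizes was not tested.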

Results

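The m6A epitranscriptome of midbrain and striatum from adult Fto knockout mice was profiled by MeRIP sequencing, in which RNA fragments bound by an m6A antibody are compared with input RNA. Fto encodes a demethylase that removes m6A from RNA, and the series asks where m6A lies in the dopaminergic circuitry of animals that lack it. The 3 MeRIP and 3 input libraries yielded 1 list of enriched regions. The list carries no value per replicate, so the counts below have no replicate error. Control mice were not analysed here, and no statement on the effect of the knockout follows from the list.

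The knockout tissue had 29950 listed m6A peaks, which together covered 4.50 Mb of the mm9 genome. All but 45 lay on chromosomes 1 to 19 and X, with 23 on the mitochondrial chromosome and 22 on 4 unplaced contigs. Chromosome Y had 0 listed peaks, but the sex of the mice and the genes of Y in mm9 are not given in the sources used here. Peaks were 100 to 200 bp long, with a mean of 150.4 bp ± 30.0 (SD over peaks) and a median of 150 bp. No peaks overlapped, but 18406 of them (61.5%) touched a neighbour end to end.

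Merging touching peaks gave 19404 separate stretches of enrichment, with a median length of 200 bp, a mean of 232.1 bp ± 146.8 (SD over stretches) and an interquartile range of 150 to 275 bp. Every stretch began and ended on a grid of 25 bp. In all 19404 stretches the number of listed peaks was the stretch length divided by 200 bp and rounded up. Of the 7860 stretches listed as more than 1 peak, 7715 had parts that differed in length by at most 2 bp, and the widest difference was 8 bp. The peaks in the list were thus equal parts of longer enriched stretches wherever a stretch exceeded 200 bp. Single peaks made up 11544 stretches (59.5%), 6001 held 2 peaks, and 1859 held 3 or more. Only 81 stretches reached 1 kb.

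Stretches of m6A enrichment lay in groups along the chromosomes. On chromosomes 1 to 19 and X, 24235 of 29905 peaks (81.0%) had another peak within 1 kb, against a mean of 2.91% and a maximum of 3.36% over 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). Touching parts of 1 stretch count as neighbours in that share. With each stretch counted once, 10487 of 19380 stretches (54.1%) had another within 1 kb, against a random mean of 2.01% (one-sided permutation p = 0.001). Over the whole list, 3289 of the 6464 gaps under 1 kb between stretches were under 200 bp, so some neighbours may be parts of 1 enriched region. With peaks within 100 bp merged, the share was 42.3%, against a random mean of 1.83%. Random placement ignores that peaks can arise only in transcribed sequence, so the test sets the list against the whole genome and not against other transcribed sequence. Joining peaks up to 5 kb apart gave 10944 clusters. Of these, 6546 clusters (59.8%) held 1 stretch, 4398 held 2 or more, 465 held 5 or more, and the richest held 19.

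**Figure D1:**
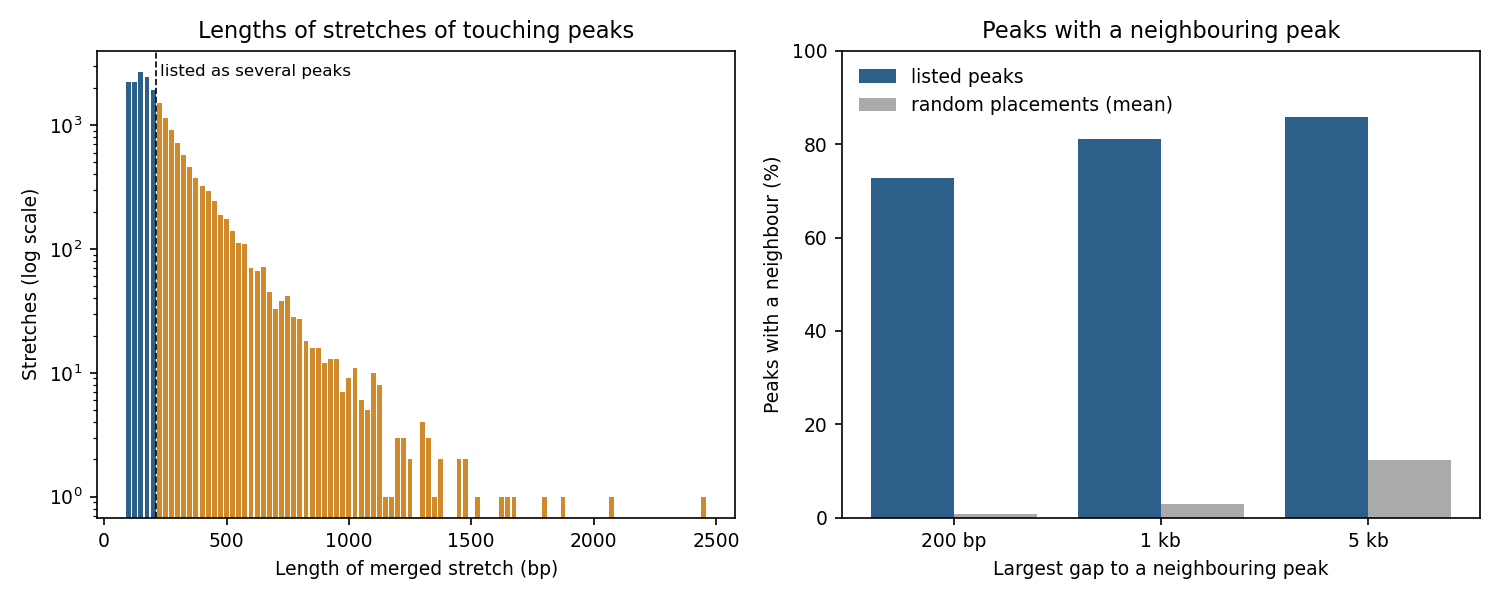
Left, number of merged stretches (log scale) by length in bp, with stretches over 200 bp, which the list divides into several peaks, in orange to the right of the dashed line. Right, percentage of peaks on chromosomes 1 to 19 and X with another peak within 200 bp, 1 kb or 5 kb (blue) and the mean of 1000 random placements (grey), where 81.0% of peaks had a neighbour within 1 kb against 2.91% at random.

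The longest continuous stretch was mitochondrial, at positions 11701 to 14150, with a length of 2450 bp. Among nuclear chromosomes, the longest stretch lay on chromosome 7 at 51716376 to 51718450, spanning 2075 bp. It was followed by a stretch of 1875 bp on chromosome 2 at 121131201 to 121133075 and one of 1800 bp on chromosome 2 at 131003601 to 131005400. The next longest were on chromosome 7 at 17395526 to 17397200 (1675 bp) and on chromosome 10 at 79774351 to 79776000 (1650 bp) and 79593401 to 79595025 (1625 bp). A stretch of 1525 bp on chromosome 2 at 121129626 to 121131150 lay just before the 1875 bp stretch of that chromosome. Merging peaks within 100 bp joins both into a region spanning at least 121129626 to 121133075, which is longer than the mitochondrial stretch. The rank of the mitochondrial stretch thus holds for touching peaks only. Stretches of 1475 bp on chromosome 12 at 109153351 to 109154825 and on chromosome 19 at 5081226 to 5082700 completed the 10 longest. These stretches were chosen after their lengths had been seen, and the genes that hold them were not assigned.

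The single densest window of m6A peaks was on chromosome 18, which held 3 of the 6 windows with the most peaks. Peaks fell into 6833 windows of 100 kb, with a median of 3 peaks per occupied window, and 79 windows held 20 or more. The window at 37800001 to 37900000 on chromosome 18 held 54 peaks in 34 stretches. The window at 37600001 to 37700000 on the same chromosome held 47 peaks, also in 34 stretches, and the one at 37900001 to 38000000 held 42 peaks in 26 stretches. On chromosome 2, the window at 121100001 to 121200000 held 48 peaks in 14 stretches, including 2 of the 10 longest stretches. On chromosome 9, the window at 108000001 to 108100000 held 47 peaks in 22 stretches. A window on chromosome 7 at 17500001 to 17600000 tied with the last of the 3 windows on chromosome 18, with 42 peaks in 21 stretches.

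Peak number followed the number of protein-coding genes over chromosomes 1 to 19 and X. Among these 20, chromosome 2 had the most peaks (2482), followed by chromosomes 11 (2449) and 7 (2229), and X had the fewest (606). Over the 20 chromosomes, peaks correlated with protein-coding genes at Pearson's r = 0.86 (two-sided permutation p = 1e-05, adjusted p = 2e-05) and Spearman's rho = 0.89 (permutation p = 1e-05, adjusted p = 2e-05). Without chromosomes 2 and 7, which lie farthest from the median gene number, r was 0.84 (permutation p = 2e-05). X lay apart from the other chromosomes, and over the 19 autosomes alone r was 0.91 (permutation p = 1e-05). The correlation with the span between the first and last peak of a chromosome was lower, at r = 0.47 (permutation p = 0.037, adjusted p = 0.037) and rho = 0.52 (permutation p = 0.021, adjusted p = 0.021). Without chromosomes 1 and 19, which lie farthest from the median span, r was 0.43 and no longer passed the threshold over 18 chromosomes (permutation p = 0.078). With span held constant, the partial correlation of peaks with gene number was 0.82 (permutation p = 1e-05).

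Autosomes had a mean of 1.45 peaks per protein-coding gene ± 0.23 (SD, n = 19 chromosomes), from 1.10 on chromosome 7 to 2.04 on chromosome 18. Chromosome X had 0.627 peaks per gene (exact Poisson 95% interval 0.578 to 0.679), which was 43.3% of the autosomal mean and below each of the 19 autosomes. X was singled out after these values had been seen, so no p-value is given for its rank. Its ratio to the autosomal mean was 71.4% when peaks within 5 kb were counted once and receptor, predicted, clone-named and multicopy genes were left out of the gene number together, still below each autosome. In that setting the exact Poisson intervals of X (0.387 to 0.492) and of chromosome 7 (0.495 to 0.570), the lowest autosome, nearly met. The mean stretch length was also lowest on X, at 200.9 bp (bootstrap 95% interval 189.9 to 212.5), against a mean over autosomes of 231.9 bp ± 7.0 (SD, n = 19 chromosomes), from 220.5 bp on chromosome 16 to 248.5 bp on chromosome 7. The interval of the difference excluded 0 against each of the 19 autosomes, the smallest difference being -19.6 bp (-34.7 to -4.18) against chromosome 16. On X, 135 of 437 stretches (30.9%, exact binomial 95% interval 26.6 to 35.5) exceeded the length of 1 listed peak, against a mean over autosomes of 40.7% ± 1.35 (SD, n = 19 chromosomes). The interval of that difference also excluded 0 against each of the 19 autosomes, the smallest being -7.08 percentage points (-12.6 to -1.43) against chromosome 3, which had 38.0%. The separate exact binomial interval of chromosome 3 (34.7 to 41.3) overlapped that of X. Clusters of peaks within 5 kb held 2.18 peaks on X, against a mean over autosomes of 2.74 ± 0.139 (SD, n = 19 chromosomes) and a lowest value of 2.54. X also had the fewest peaks per Mb of span, 3.77 against 8.32 to 20.7 on the autosomes. Joining within 5 kb depends on how densely peaks lie, so the cluster values may partly reflect this spacing, which was not tested. Stretch length sets the number of listed peaks in a stretch. These length and cluster measures are therefore not independent of each other or of the peaks per gene by which X was singled out.

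**Figure D2:**
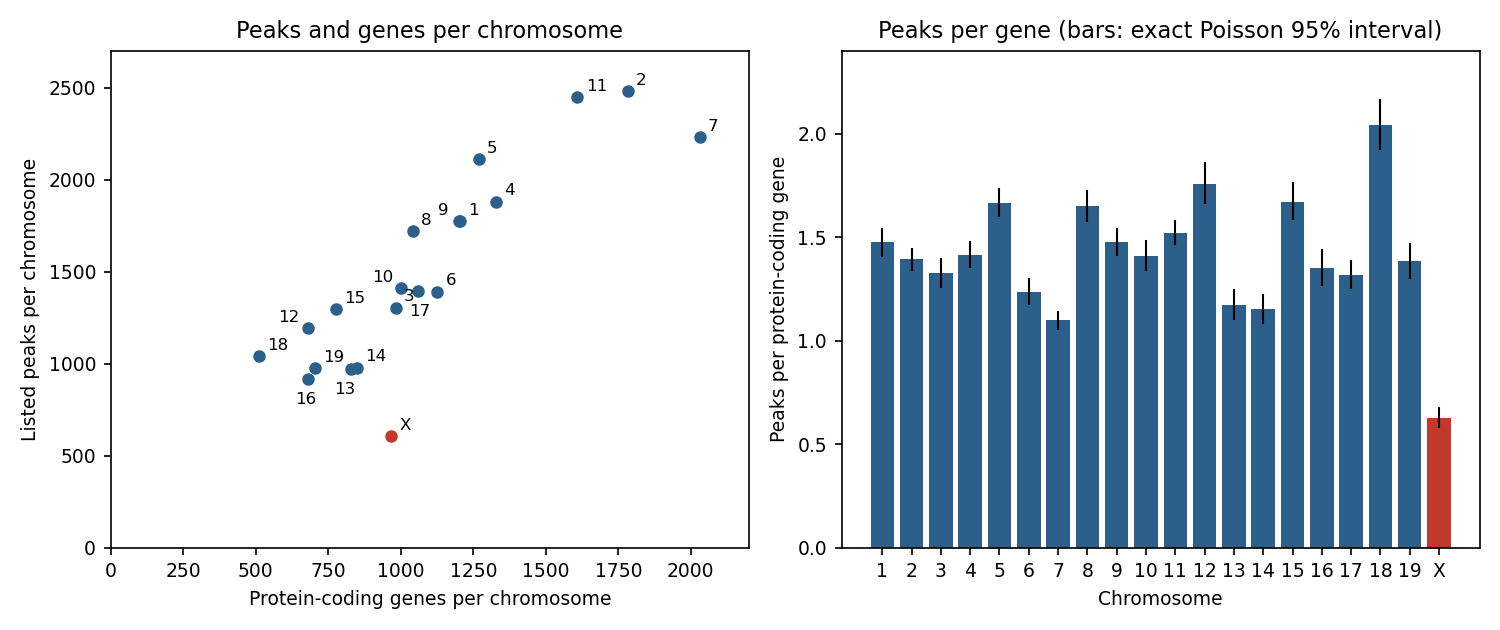
Left, listed m6A peaks against protein-coding genes for chromosomes 1 to 19 (blue) and X (red), 1 point per chromosome. Right, peaks per protein-coding gene for each chromosome with exact Poisson 95% intervals, where X (0.627) lies below all autosomes (1.10 to 2.04).

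The mitochondrial chromosome had 23 peaks in 6 stretches that covered 4225 bp. The first 3 stretches, at 4551 to 4725, 4926 to 5100 and 5151 to 5275, were short and covered 475 bp. After 5700 bp without a peak, the remaining 3 stretches, at 10976 to 11475, 11701 to 14150 and 14576 to 15375, covered 3750 bp, or 85.2% of the 4400 bp they spanned. No peak was listed before position 4551 or after 15375. The list has no height, strand or input value, so whether these stretches reflect m6A on mitochondrial RNA was not tested.

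**Figure D3:**
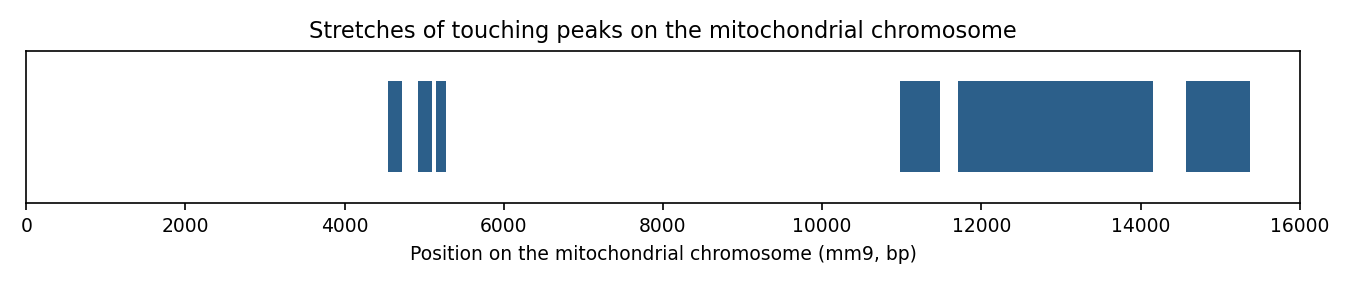
Position in bp on the mitochondrial chromosome (mm9) of the 6 stretches of touching m6A peaks, drawn to scale as blue boxes; the right edge of the axis is not the end of the chromosome. Most of the covered length lies between 10976 and 15375.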

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

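Peaks outside the chromosomes used for the comparison with gene number were flagged because they lie in otherwise unused data. The mitochondrial chromosome held 23 peaks, including the longest stretch of touching peaks in the list at 2450 bp. The 4 unplaced contigs held 22 peaks, of which 15 lay on the contig assigned to chromosome 1.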

How the results depend on the processing

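The number of enriched regions depended on how touching peaks were treated. The 29950 listed peaks became 19404 regions when touching peaks were merged and 17160 when peaks within 100 bp were merged, and 17469 peaks were at or above the median length. Because stretches over 200 bp are divided, that cut drops the parts of stretches of 225 to 275 bp but keeps single stretches of 150 bp. It therefore does not select longer enriched stretches. Merging touching peaks undoes the equal division of long stretches, while merging within 100 bp also joins stretches that the list keeps apart. Leaving out the longest peaks, which removed all 2969 peaks of 200 bp (9.91%), left 26981. A minimum length of 100 bp removed no peak and tests nothing, although it is counted among the alternatives of each result below. The correlation of peaks with gene number stayed between 0.84 and 0.94 under 11 alternatives, and the share of peaks with a neighbour within the set distance stayed above its random placements under 7, from 42.3% to 85.9%. Chromosome X had between 0.379 and 0.714 of the autosomal mean per gene under 12 alternatives, chosen after seeing the data, and no autosome was at or below it in any of them. The lowest ratio, 0.379, came from the cut at the median length. With receptor, predicted, clone-named and mainly X-linked multicopy genes left out of the gene number, but their peaks kept, the ratio rose from 0.433 to 0.566, and to 0.630 or 0.714 when touching peaks or peaks within 5 kb were also merged. Read depth, transcript level and the peak threshold limit what an unlisted gene or chromosome means, and none of them can be read from the list. No paired analysis was possible because the list gives no value per replicate, and no replicate could be left out for the same reason. Alternatives for transcript position, motif, gene lists and score were not run.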

Other observations

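All tests in this part were chosen after the values they concern had been seen. Chromosome 18 carries all 57 protein-coding genes of the clustered protocadherin families (Pcdha, Pcdhb and Pcdhg) in the gene table, cell-adhesion genes arranged in tandem, with up to 30 of them in an uninterrupted row. It also holds 3 of the 6 windows of 100 kb with the most peaks, with 143 peaks in 94 stretches. Whether the windows and the gene clusters coincide was not tested, because the gene table and the peak list are on different builds.

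Among chromosomes 1 to 19 and X, chromosome 18 had the most peaks per protein-coding gene, 2.04. With peaks within 5 kb counted once, it had 0.669 per gene beside 0.651 on chromosome 12. With receptor, predicted, clone-named and multicopy genes also left out, chromosome 12 was highest, at 0.750 against 0.722 on chromosome 18. A candidate explanation for the lead of chromosome 18 in listed peaks is its densest windows. Without the 143 peaks of these windows, chromosome 18 kept 898 peaks over its 510 genes, or 1.76 per gene (exact Poisson 95% interval 1.65 to 1.88). Chromosome 12, the next autosome, kept all its peaks and had 1.76 (1.66 to 1.86). The windows were picked for their peak number in this same list and removed from chromosome 18 only, so a fall was built in. If the windows held the 57 protocadherin genes, which was not tested, leaving these out too would give 1.98 (1.85 to 2.12). Leaving out only some of the 57 genes would give a value between these 2. The contribution of the windows stays open, because the value depends on the genes they hold and the fall was built in. No biological explanation was tested.

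Peaks per gene varied among autosomes with a coefficient of variation of 16.1%. One hypothesis is that olfactory and vomeronasal receptor genes, which are mainly transcribed in chemosensory epithelia, lower the value of chromosomes rich in them. Over the 19 autosomes, peaks per gene fell with the percentage of such genes (Pearson's r = -0.60, two-sided permutation p = 0.0071, and Spearman's rho = -0.65, permutation p = 0.0037). Without chromosomes 7 and 2, where receptors make up 20.6% and 16.1% of protein-coding genes, r was -0.59 (permutation p = 0.012). Receptor genes are counted in both measures, in the gene number and in the percentage, which the permutations ignore. A negative correlation can arise from this shared count, so these p-values do not test the hypothesis. Peaks in receptor genes could not be counted. Leaving the receptor genes out lowered the coefficient of variation to 13.1%, so they may account for a part of the differences and most of the spread remained.

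Chromosome X had the fewest peaks per protein-coding gene among chromosomes 1 to 19 and X, and predicted, clone-named, chemosensory and multicopy genes in the gene number do not account for the whole deficit: all X peaks over the remaining genes gave 0.953 (exact Poisson 95% interval 0.878 to 1.03) against 1.38 (1.29 to 1.46) on the lowest autosome, with the peaks of the genes left out still counted. The division of long stretches does not account for the whole either, with 0.452 stretches per gene (0.411 to 0.497) against 0.678 (0.642 to 0.715). With both changes X had 0.630 of the autosomal mean, compared with 0.433. With peaks within 5 kb counted once in place of stretches, it had 0.714. That was 0.437 per remaining gene (0.387 to 0.492) against 0.531 (0.495 to 0.570) on chromosome 7, the lowest autosome. These exact Poisson intervals nearly meet and are too narrow, so this last difference is uncertain. Joining within 5 kb also depends on how densely peaks lie, which differed between X and the autosomes. Fewer X genes with peaks as the only difference would leave the mean stretch length on X inside the autosomal range. That length was 200.9 bp on X against 231.9 bp ± 7.0 over the autosomes. This prediction was written after the lengths had been seen, so the result is at most weak evidence against that explanation. The interval of the difference was below 0 for each of the 19 autosomes, although the separate intervals of X and chromosome 16 overlap. All these differences share the same X stretches, so they are not independent of each other. Stretch length also enters the listed peaks per gene by which X was singled out, so it is not independent of that choice. Fewer X genes with peaks can still be a part of the deficit. Lower levels of X transcripts and fewer m6A sites per X transcript could both lower the percentage of stretches over 200 bp, 30.9% against 40.7% ± 1.35. Both predictions were the same and were written after that percentage had been seen, so it is no evidence for either. The list has no transcript level to separate them, and other causes of shorter stretches were not tested. A lower density of m6A on X-linked transcripts is a hypothesis only, which X transcript levels in the input libraries would test, and whether it depends on Fto was not tested.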
